A study of Rattus norvegicus with 17 samples.

How the data were processed

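The 17 samples were ChIP-seq libraries from wild-type Sprague-Dawley rat cells, and each had 1 file of peaks. Per the labels' protocols, cells from the cortices of pups at postnatal day 2 were isolated by differential detachment. The growth medium contained bFGF at 20 ng/ml and PDGF-AA at 10 ng/ml, and the differentiation medium contained ciliary neurotrophic factor at 10 ng/ml and T3 at 15 nM. Nuclei were sonicated, antibody-bound chromatin was isolated and fragment libraries for SOLiD sequencing were made, per the labels' protocols. Each sample was assigned to its target and stage from its title. The times in culture at which iOL and mOL were taken are not given in the sources used here. The protocol text calls the isolated cells by the name of the immature stage, so the stage names follow the sample labels.

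MACS version 1.4.0 and genome build rn4 are named in the submitters' processing notes, without their settings. The aligner, the p-value threshold of peak calling, any control library, any filter and any pooling of cultures or lanes are not given in the sources used here. Each deposited file held 3 columns, the chromosome, start and end of each peak in base pairs, with no score, height, fold or p-value and no header. The values analysed were therefore the positions and widths of the authors' peaks. Of the lists, 9 were sorted by position and 8 were not, and what the order of the latter means is not given in the sources used here. Read numbers were not analysed here, so the depth of each library is unknown. A more deeply sequenced library or a looser threshold gives a longer list, and this enters every comparison of peak numbers and of shared peaks.

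Starts were written as 1-based positions by adding 1. Peaks were used as called, and overlap meant at least 1 bp in common. For each list the number and width of peaks and the length covered were computed. Shares of 1 list meeting another were given with exact Clopper-Pearson 95% intervals, and where a count was 0 with the limit that 3 counts would give. These intervals treat peaks as independent and cover counting error only. Chance overlap came from 1000 circular shifts of each list along its chromosomes with a fixed seed, taking the largest peak end over the 17 lists as the length of a chromosome. Each Brg1, Olig2 and RNAPII peak was placed in 1 class by marks of its own stage, in the order H3K4me3, H3K27Ac without H3K4me3, H3K9me3 alone, none. A peak counted as kept when it met a peak of the same target at the other stage, and otherwise as gained or lost. Odds ratios over H3K27Ac peaks have Woolf 95% intervals over regions. Domains were H3K27Ac peaks joined across gaps of up to 12.5 kb.

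The comparisons, the overlap rule, the chance model and the alternatives were fixed before the data were examined. With 1 library for each target and stage, no test between stages could be made. Regions to be named were, for each stage, the 3 highest-scoring peaks of Brg1, Olig2, Brg1 with Olig2, RNAPII and each mark compared, and the 3 longest domains, leaving out unplaced sequence. As the files hold no score, the 3 widest peaks took the place of the highest-scoring ones, a choice made after the files had been seen, and the text gives a selection of them. The domain rule was applied as planned. The splits of Olig2 peaks by Brg1 and of Brg1 peaks by Olig2, the comparison of domains by length, the equal-length H3K27Ac lists and the use of width as a stand-in for score were also added after the files had been seen. A planned comparison of gene lists near transcription starts was left out: the annotation table at hand is of another rat assembly (GRCr8), and positions were not converted between builds. The mouse spinal cord RNA profiles named in the study's design were not analysed here.

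The overlap and chance calculations were tested on simulated lists with known overlap before use. Planted overlaps of 0, 20 and 60% of the Brg1 peaks were recovered with errors of at most 0.505 percentage points for the 452 OPC peaks, 0.330 for the 5465 iOL peaks and 0.0509 for the 4378 mOL peaks. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9; overlap counts were checked against bedtools 2.31.1 on 8 pairs of lists. Alternatives tried were overlap of 50% of the shorter peak, peaks within 1000 bp, lists without unplaced sequence, merged peaks, marks of any stage, other random placements and odds ratios within quartiles of H3K27Ac width. Added after seeing the data were the wider 50% of each list, the middle 200 bp of each peak and H3K27Ac lists of equal length. Where Brg1, Olig2 or RNAPII was set against a mark, the wider 50% and the middle 200 bp were taken of the factor lists only. The mark lists were then left whole. Equal length means an equal number of peaks, not equal sequence covered.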

Results

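Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map 6 targets in primary rat cells of the oligodendrocyte lineage, the glia that form myelin in the central nervous system. The cells came from the cortices of Sprague-Dawley pups at postnatal day 2. Oligodendrocyte precursor cells (OPC) carried the label of mitogen treatment. Immature (iOL) and mature oligodendrocytes (mOL) carried the label of treatment with triiodothyronine (T3), the thyroid hormone that drives precursors out of the cell cycle and into differentiation. The targets were Brg1 (encoded by Smarca4), the ATPase of the BAF chromatin remodelling complex; Olig2, a basic helix-loop-helix transcription factor of the lineage; RNA polymerase II (RNAPII); and 3 histone marks. H3K27Ac is found at active enhancers and promoters, H3K4me3 at promoters, and H3K9me3 in silenced chromatin. Each of the 17 libraries gave 1 peak list, with 1 library for each target and stage and RNAPII mapped in OPC and iOL. No difference between stages therefore has a replicate check, and no p-value between stages is given. Percentages carry exact Clopper-Pearson 95% intervals, which cover the counting error of peaks in these lists alone. The lists give positions in rat build rn4 without read numbers, so the depth of each library is unknown.

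The first comparison asked how many places each target occupied at each stage. Brg1 had 452 peaks in OPC, 5465 in iOL and 4378 in mOL, so the iOL list was 12.1 times as long as the OPC list. Olig2 had 21901 peaks in OPC, 25787 in iOL and 2759 in mOL, a list 9.35 times shorter in mOL than in iOL. RNAPII had 332 peaks in OPC and 1425 in iOL, a ratio of 4.29. The mark of active chromatin was most widely called in mOL, where H3K27Ac had 35268 peaks over 38.6 Mb, against 19130 peaks over 17.9 Mb in OPC and 21589 over 21.7 Mb in iOL. H3K4me3 had 11758 peaks in OPC, 10467 in iOL and 17530 in mOL. H3K9me3 had 3149 peaks in OPC, 827 in iOL and 7103 in mOL. Peak number moves with depth as well as with occupancy, and the lists alone do not separate these. The OPC Olig2 list also differed in form from the others. It had no peak narrower than 703 bp and a median width of 1312 bp against 720 bp in iOL. Joining peaks of this list that overlapped or touched lowered their number by 364.

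**Figure D1:**
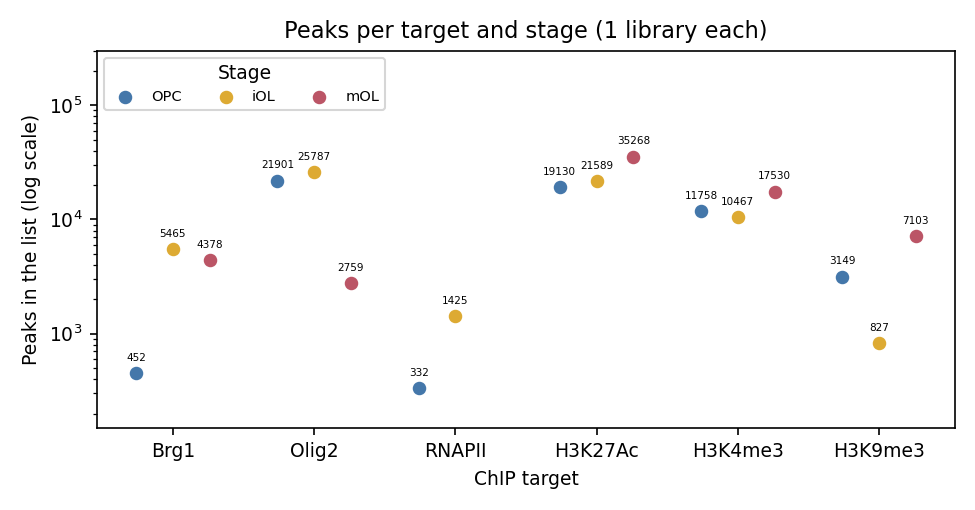
Number of peaks (y axis, log scale) for each ChIP target (x axis) in OPC, iOL and mOL; each point is 1 library. The Brg1 list goes from 452 peaks in OPC to 5465 in iOL, while the Olig2 list goes from 25787 in iOL to 2759 in mOL.

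Peaks of each target were then compared between stages, to see whether the lists marked the same places. Nearly all Brg1 sites of OPC were Brg1 sites in iOL too: 450 of 452 OPC peaks (99.6%, 98.4 to 99.9) met an iOL peak, against a mean of 0.516% over random shifts along the chromosomes. In the other direction 8.34% (7.62 to 9.11) of iOL Brg1 peaks met an OPC peak. Between iOL and mOL, 39.8% (38.5 to 41.1) of iOL peaks met an mOL peak and 50.2% (48.7 to 51.7) of mOL peaks met an iOL peak. Of 7633 regions with Brg1 at any stage, 301 had it at all 3 stages, 3141 in iOL alone and 2180 in mOL alone.

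Olig2 sites were shared widely between OPC and iOL, and the short mOL list lay almost wholly inside them. An iOL Olig2 peak was met by 71.6% (71.0 to 72.2) of OPC Olig2 peaks, and an OPC peak by 61.4% (60.8 to 62.0) of iOL peaks. Of the mOL Olig2 peaks, 92.8% (91.7 to 93.7) met an iOL peak and 89.1% (87.9 to 90.2) an OPC peak, while 9.97% (9.61 to 10.3) of iOL peaks met an mOL peak. RNAPII peaks of OPC met an iOL RNAPII peak in 65.1% (59.7 to 70.2) of cases. The RNAPII value was 37.1% with the wider 50% of each list and 42.2% with each peak reduced to its middle 200 bp.

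The histone marks were compared between stages in the same way. H3K4me3 peaks of OPC met an iOL H3K4me3 peak in 82.8% (82.1 to 83.5) of cases and an mOL peak in 98.6% (98.4 to 98.8), and 99.5% (99.3 to 99.6) of iOL peaks met an mOL peak. For H3K27Ac, 76.3% (75.7 to 76.9) of OPC peaks met an iOL peak and 87.8% (87.4 to 88.3) of iOL peaks met an mOL peak. Many places of both marks were called in mOL alone: 14027 of 37372 H3K27Ac regions and 5942 of 17241 H3K4me3 regions. A more sensitive mOL library would also give such calls, and the lists do not separate this from places added in mOL. H3K9me3 shares were lower: 6.95% (6.09 to 7.90) of OPC peaks met a peak of the iOL list, which holds only 827, and 34.4% (32.7 to 36.1) met an mOL peak, with 44.4% (41.0 to 47.8) of iOL peaks met by an mOL peak, and 162 of 9540 regions called at all 3 stages. Reducing each peak to its middle 200 bp gave 54.6% for H3K27Ac and 65.9% for H3K4me3 from iOL to mOL, and 65.5% for H3K4me3 from OPC to mOL. For H3K9me3 it gave 3.46% from OPC to iOL, 19.8% from OPC to mOL and 20.1% from iOL to mOL.

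The title of the study names a partnership of Brg1 with Olig2, so the overlap of these factors was measured at each stage. In OPC, 433 of 452 Brg1 peaks met an Olig2 peak (95.8%, 93.5 to 97.5), where random shifts gave 2.25%. In iOL it was 4026 of 5465 (73.7%, 72.5 to 74.8; random shifts 1.79%), and in mOL 957 of 4378 (21.9%, 20.6 to 23.1; random shifts 0.177%). The lower mOL value went with the short mOL Olig2 list: 68.6% (67.2 to 70.0) of mOL Brg1 peaks met an iOL Olig2 peak and 62.7% (61.2 to 64.1) an OPC Olig2 peak. Most Olig2 sites had no Brg1 peak. Brg1 of the same stage was found at 2.08% (1.90 to 2.28) of Olig2 peaks in OPC, 15.9% (15.5 to 16.4) in iOL and 34.1% (32.3 to 35.9) in mOL. Among 33544 regions with either factor at any stage, 5663 had Brg1 at some stage and Olig2 at the same or another stage, 1912 had Brg1 without Olig2 at any stage, and 129 had both at all 3 stages.

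**Figure D2:**
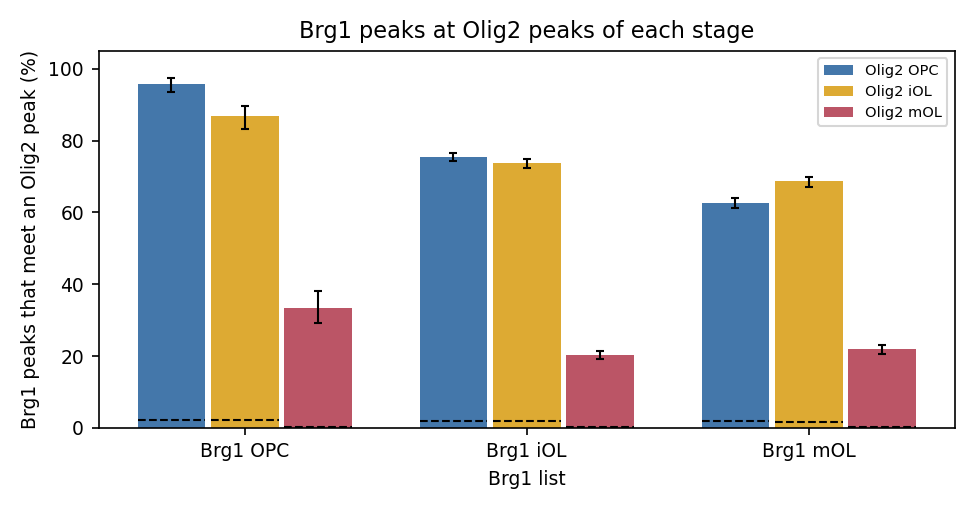
Percentage of Brg1 peaks of each stage (x axis) that met an Olig2 peak of OPC, iOL or mOL (bar colour); error bars are exact 95% intervals for counting error and dashed lines the mean of random shifts. Brg1 peaks of mOL met Olig2 peaks of iOL in 68.6% of cases and Olig2 peaks of mOL in 21.9%.

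The overlap was also measured within acetylated regions. Among H3K27Ac peaks of OPC, Brg1 was present at 6.30% (5.68 to 6.96) of those with Olig2 and at 0.0524% (0.0211 to 0.108) of those without, an odds ratio of 128 (60.7 to 271). In iOL the shares were 33.9% (32.9 to 35.0) and 3.11% (2.83 to 3.41), an odds ratio of 16.0 (14.4 to 17.8). In mOL they were 60.9% (58.3 to 63.5) and 8.84% (8.54 to 9.14), an odds ratio of 16.1 (14.4 to 18.0). Among H3K27Ac peaks free of H3K4me3 the odds ratios were 88.4 (33.0 to 237), 10.3 (9.11 to 11.7) and 9.44 (8.40 to 10.6). These intervals count regions, not cultures. The OPC odds ratio rests on 7 acetylated regions with Brg1 and no Olig2 and was 81.9, 77.4, 63.7 and 35.1 under other rules of overlap or peak width. Against random placement inside acetylated or H3K4me3-marked regions, in place of shifts along whole chromosomes, the overlap was 3.19 times the chance value in OPC, 2.09 times in iOL and 6.97 times in mOL, where the shifts had given 42.6, 41.2 and 123. The observed overlap took in all Brg1 peaks, of which 31.4% in OPC, 50.4% in iOL and 24.0% in mOL met none of the marks. These ratios are therefore not an enrichment within marked regions alone. The mOL ratios also rest on the short mOL Olig2 list, for which random shifts gave 0.177%.

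Olig2 sites that also held Brg1 were acetylated more often than Olig2 sites that did not, at each stage. H3K27Ac of the same stage was present at 70.2% (65.7 to 74.3) of the 456 OPC Olig2 peaks with Brg1 and 21.9% (21.4 to 22.5) of the 21445 without. The iOL values were 57.2% (55.6 to 58.7) of 4100 and 21.4% (20.9 to 22.0) of 21687, and the mOL values 72.5% (69.5 to 75.3) of 941 and 24.3% (22.3 to 26.3) of 1818. The reverse split, of Brg1 peaks by Olig2, depended in mOL on the Olig2 lists used. Brg1 peaks of OPC were acetylated in 69.7% (65.2 to 74.0) of cases with Olig2 of the same stage and in 7 of 19 without it. Brg1 peaks of iOL were acetylated in 57.2% (55.6 to 58.7) of cases with Olig2 and 26.9% (24.6 to 29.3) without it, whereas those of mOL were acetylated in 72.7% (69.8 to 75.5) and 76.6% (75.2 to 78.1). With Olig2 of any stage counted, the mOL shares were 78.3% (76.9 to 79.7) with Olig2 and 68.4% (65.6 to 71.2) without, and the iOL shares 54.0% (52.6 to 55.5) and 26.7% (23.9 to 29.6). Olig2 peaks with Brg1 were the wider ones, with a median of 864 bp against 697 bp in iOL. With the 19130 widest H3K27Ac peaks of each stage, the mOL shares were 58.9% with Brg1 and 14.9% without. With the wider 50% of the Olig2 and Brg1 lists, the shares with and without Brg1 were 87.2% and 36.0% in OPC and 75.4% and 33.9% in iOL.

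The marks at the peaks were used to describe the chromatin in which each factor was found. Brg1 lay in chromatin of enhancer type, that is H3K27Ac without H3K4me3, at 66.2% (61.6 to 70.5) of OPC, 45.1% (43.8 to 46.5) of iOL and 70.0% (68.7 to 71.4) of mOL peaks. H3K4me3 was present at 2.21% (1.07 to 4.03), 4.45% (3.92 to 5.03) and 5.94% (5.26 to 6.68) of these peaks. None of the measured marks was found at 31.4% (27.2 to 35.9) of OPC, 50.4% (49.1 to 51.7) of iOL and 24.0% (22.7 to 25.3) of mOL Brg1 peaks, and in iOL this was the largest class as called. It was not the largest in the wider 50% of the iOL list, where 31.5% (29.7 to 33.3) were unmarked, or with marks of any stage counted, where 31.8% (30.6 to 33.1) were. The wider 50% of the OPC and mOL lists were unmarked in 14.6% (10.3 to 19.9) and 10.5% (9.21 to 11.8) of cases, and 18.1% (14.7 to 22.0) of OPC peaks met no mark of any stage. Olig2 was found mainly outside the measured marks as called, with no mark of the same stage at 76.3% (75.8 to 76.9) of OPC, 72.5% (71.9 to 73.0) of iOL and 58.2% (56.3 to 60.1) of mOL peaks. Its enhancer-type share was 20.8% (20.3 to 21.3) in OPC, 24.7% (24.2 to 25.2) in iOL and 38.7% (36.9 to 40.5) in mOL. RNAPII sat at promoters: H3K4me3 was present at 70.8% (65.6 to 75.6) of OPC and 73.3% (70.9 to 75.5) of iOL peaks. None of the 452 Brg1 peaks of OPC met 1 of the 332 OPC RNAPII peaks. The exact upper limit of this share is 0.813%, and 3 counts would give 0.664%. In iOL, 1.26% (0.984 to 1.60) of Brg1 peaks met an iOL RNAPII peak. The enhancer-type share of OPC Olig2 peaks was 34.2% in the wider 50% of the list and 33.5% with marks of any stage counted. Counting marks of any stage also gave H3K4me3 at 7.96% of OPC and 8.86% of iOL Brg1 peaks, and at 4.90% of OPC and 5.73% of iOL Olig2 peaks.

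**Figure D3:**
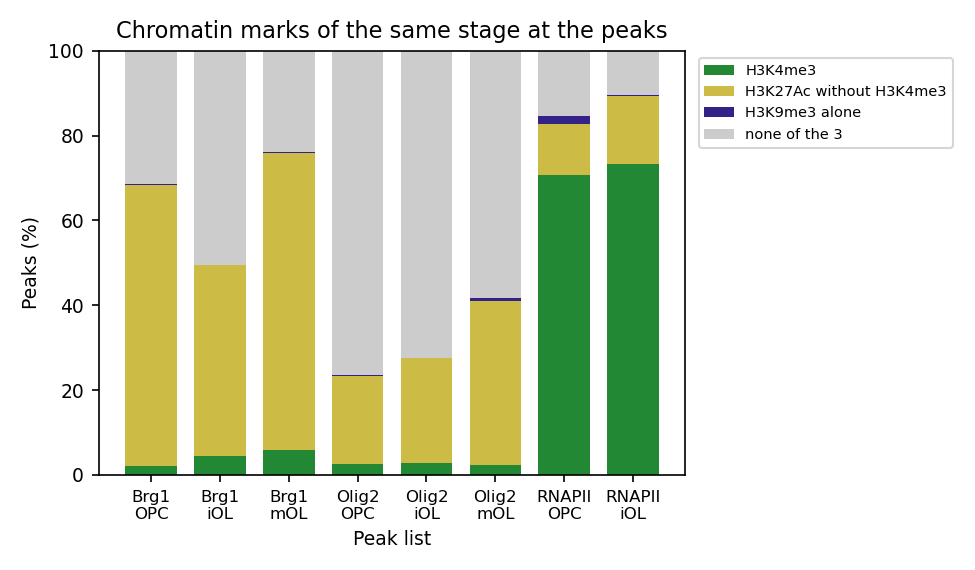
Percentage of the peaks of each list (x axis) in 4 classes by marks of the same stage; colours stand for H3K4me3, H3K27Ac without H3K4me3, H3K9me3 alone and none of the 3 marks. RNAPII peaks fall mainly in the H3K4me3 class (70.8% in OPC, 73.3% in iOL), and Brg1 peaks have a larger H3K27Ac class than Olig2 peaks of the same stage.

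The sites called for Brg1 in iOL and not in OPC were asked for their state in OPC. The OPC Brg1 list held only 452 peaks. Brg1 present in OPC but not called there therefore cannot be told apart from a gain in iOL. Of the 5009 iOL Brg1 peaks with no OPC Brg1 peak, 73.7% (72.4 to 74.9) met an Olig2 peak in OPC and 42.4% (41.0 to 43.8) an H3K27Ac peak in OPC. In iOL the same sites met Olig2 in 72.5% (71.3 to 73.7) of cases and H3K27Ac in 48.0% (46.6 to 49.4). Acetylation at both stages was found at 34.4% (33.1 to 35.8) of them, acetylation in iOL alone at 13.6% (12.6 to 14.6), and acetylation in OPC alone at 7.97% (7.23 to 8.75). The 456 iOL peaks already bound by Brg1 in OPC met OPC Olig2 in 95.6% (93.3 to 97.3) of cases and OPC H3K27Ac in 68.6% (64.2 to 72.9).

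From iOL to mOL the gained Brg1 sites differed from the kept ones in Olig2 and in the timing of acetylation. The 2197 mOL peaks kept from iOL met iOL Olig2 in 86.8% (85.3 to 88.2) of cases, and the 2181 gained peaks in 50.3% (48.1 to 52.4). Acetylation in mOL was found at 79.3% (77.6 to 81.0) of kept and 72.2% (70.3 to 74.1) of gained peaks. Acetylation that was called in mOL and not in iOL was found at 34.3% (32.3 to 36.4) of gained and 14.2% (12.8 to 15.7) of kept peaks, and with the 19130 widest H3K27Ac peaks of each stage at 24.1% (22.3 to 25.9) and 9.33% (8.15 to 10.6). The opposite change, from acetylated in iOL to not in mOL, was then found at 4.86% (4.00 to 5.85) of gained and 9.29% (8.10 to 10.6) of kept peaks. Acetylation in iOL was found at 69.1% (67.1 to 71.0) of kept and 39.7% (37.6 to 41.7) of gained peaks. In the wider 50% of each Brg1 list, with the H3K27Ac list left whole, it was found at 61.4% of gained peaks. There, gained meant without a peak in the wider 50% of the iOL list, and the share of kept peaks was not computed. Among peaks without acetylation in iOL, it was found in mOL at 56.9% (54.2 to 59.6) of 1316 gained and 45.9% (42.2 to 49.8) of 679 kept peaks. With these lists of equal length the shares were 38.7% (36.1 to 41.3) of 1358 and 28.5% (25.2 to 31.9) of 720, and acetylation in mOL was found at 56.9% (54.8 to 59.0) of all gained and 67.3% (65.3 to 69.2) of all kept peaks. At the 3292 iOL Brg1 sites without an mOL peak, acetylation was present at 35.9% (34.3 to 37.6) in iOL and 45.8% (44.1 to 47.6) in mOL, and at 34.2% (32.6 to 35.8) and 33.3% (31.7 to 34.9) with the lists of equal length.

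The mOL H3K27Ac list was the longest, so the 19130 widest H3K27Ac peaks of each stage were also compared. These lists are equal in number of peaks and not in sequence covered, since the narrowest iOL and mOL peaks were left out. With lists of equal length, Brg1 peaks of mOL met H3K27Ac of OPC in 37.2% (35.8 to 38.7), of iOL in 52.5% (51.0 to 54.0) and of mOL in 62.1% (60.7 to 63.6) of cases. Brg1 peaks of iOL met it in 44.6% (43.3 to 45.9), 47.4% (46.1 to 48.7) and 46.7% (45.4 to 48.1). Olig2 peaks of OPC stayed between 22.5% (21.9 to 23.0) and 23.8% (23.2 to 24.3) in the 3 stages, and Olig2 peaks of iOL between 22.2% (21.7 to 22.7) and 25.8% (25.2 to 26.3). Olig2 peaks of mOL met it in 22.1% (20.5 to 23.7), 30.8% (29.1 to 32.6) and 29.9% (28.2 to 31.6).

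**Figure D4:**
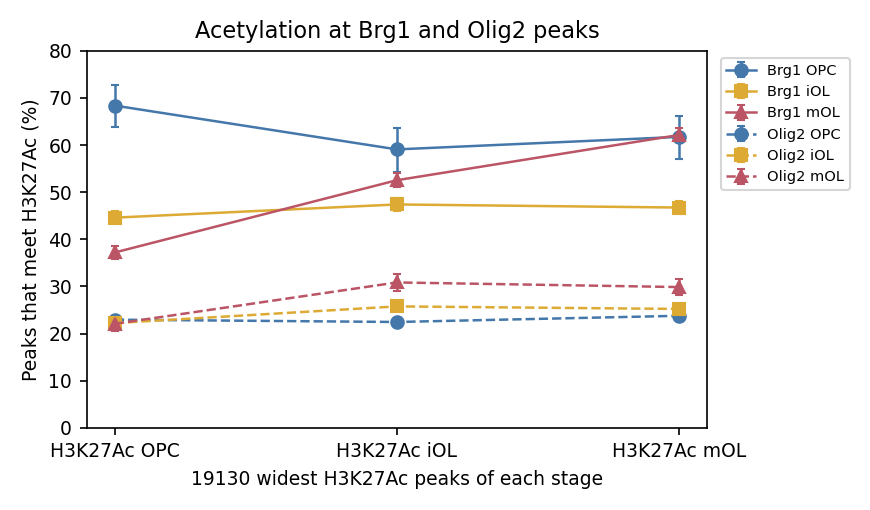
Percentage of Brg1 peaks (solid lines) and Olig2 peaks (dashed lines) of each stage that met 1 of the 19130 widest H3K27Ac peaks of OPC, iOL or mOL (x axis); error bars are exact 95% intervals for counting error. Brg1 peaks of mOL go from 37.2% with OPC acetylation to 62.1% with mOL acetylation.

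Olig2 sites were followed in the same way. The 15825 iOL Olig2 peaks kept from OPC held iOL Brg1 in 23.5% (22.8 to 24.2) of cases, and the 9962 gained after OPC in 3.82% (3.46 to 4.22). The 6211 OPC Olig2 peaks without an iOL Olig2 peak held iOL Brg1 in 7.45% (6.81 to 8.14). Acetylation in iOL was found at 29.8% (29.0 to 30.5) of kept and 22.9% (22.1 to 23.8) of gained peaks. Between iOL and mOL, the 2559 kept Olig2 peaks held mOL Brg1 in 36.4% (34.5 to 38.3) of cases, against 8.96% (8.59 to 9.33) of the 23216 iOL peaks without an mOL Olig2 peak. Sites without Olig2 in mOL were acetylated in 26.2% (25.7 to 26.8) of cases in iOL and 32.9% (32.3 to 33.5) in mOL, and in 24.9% (24.4 to 25.5) and 24.5% (23.9 to 25.04) with H3K27Ac lists of equal length.

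RNAPII peaks called in iOL and not in OPC lay mainly at places that carried active marks in OPC. The OPC RNAPII list held 332 peaks and met 2.60% (2.32 to 2.91) of OPC H3K4me3 peaks. RNAPII present in OPC but not called there therefore cannot be told apart from a gain in iOL. Of the 1211 iOL RNAPII peaks with no OPC RNAPII peak, 85.1% (83.0 to 87.1) met H3K27Ac and 72.7% (70.1 to 75.2) met H3K4me3 in OPC, close to the 87.0% (84.9 to 88.8) and 72.2% (69.6 to 74.7) found in iOL. Brg1 of iOL was present at 5.62% (4.39 to 7.06) of the gained and at 1 of the 214 kept RNAPII peaks. Olig2 of iOL was present at 16.4% (14.4 to 18.6) of gained and 4.67% (2.26 to 8.43) of kept peaks.

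Long stretches of acetylated chromatin were built by joining H3K27Ac peaks up to 12.5 kb apart, which gave 11194 domains in OPC, 12042 in iOL and 17186 in mOL. Brg1 and Olig2 were found more often in the longest than in the shortest domains. Brg1 of the same stage was present in 4.32% (3.60 to 5.14) of the longest 2799 OPC domains and 0.929% (0.608 to 1.36) of the shortest 2799, in 31.1% (29.4 to 32.8) and 11.3% (10.2 to 12.5) of 3011 each in iOL, and in 29.3% (27.9 to 30.6) and 7.61% (6.83 to 8.44) of 4297 each in mOL. Olig2 was present in 67.7% (66.0 to 69.4) of the longest and 34.2% (32.5 to 35.9) of the shortest of these iOL domains. A longer domain offers more sequence in which a peak can fall, with medians of 9.27 kb and 0.545 kb in these iOL groups.

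The longest mOL domain, at chromosome 20:43500962-43645664 (144.7 kb), held 9 H3K27Ac peaks in OPC, 32 in iOL and 41 in mOL. It held no Brg1 peak in OPC, 2 in iOL and 3 in mOL, beside 7, 11 and 0 Olig2 peaks. The next, at chromosome 5:70867110-70976210, held 8, 17 and 33 H3K27Ac peaks and 0, 4 and 8 Brg1 peaks, with 7, 11 and 1 Olig2 peaks. At chromosome 3:34428050-34527875 there were 3, 5 and 21 H3K27Ac peaks, 0, 3 and 6 Brg1 peaks, and 3, 8 and 1 Olig2 peaks, with no H3K4me3 peak at any stage. Not every long domain gained Brg1. The domain at chromosome 12:32561992-32640385, among the longest in OPC, held 16, 17 and 18 H3K27Ac peaks and 6, 9 and 0 Olig2 peaks and no Brg1 peak at any stage. The longest OPC domain, at chromosome 7:117122858-117213722 (90.9 kb), held 17, 15 and 23 H3K27Ac peaks, 3 iOL RNAPII peaks and 1 Brg1 peak each in iOL and mOL. An iOL domain at chromosome 19:28979201-29053917 held 5 Brg1 peaks in each of iOL and mOL and none in OPC. Genes at these positions are not named, since no gene annotation of build rn4 was used here.

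**Figure D5:**
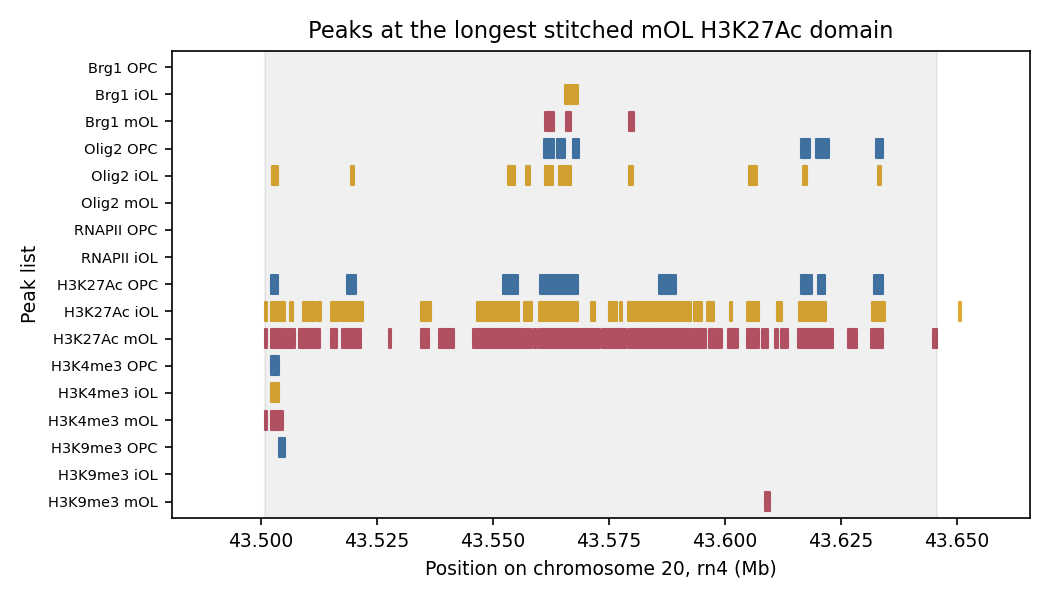
Peaks of all 17 lists (rows) along the longest stitched mOL H3K27Ac domain on chromosome 20 (x axis, position in Mb, build rn4); each box is 1 peak drawn to scale and the grey band is the domain. H3K27Ac peaks number 9 in OPC, 32 in iOL and 41 in mOL, and Brg1 peaks 0, 2 and 3.

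Single sites were named by peak width, because the lists carry no score. Width need not follow peak strength. In the unsorted mOL Brg1 list, the first 438 peaks had a median of 767 bp and the last 437 a median of 1099 bp. The narrower first group met iOL Brg1 more often, in 66.0% (61.3 to 70.4) of cases against 42.8% (38.1 to 47.6). The widest iOL Brg1 peak, at chromosome 1:173743078-173748524 (5.45 kb), met Brg1 and Olig2 peaks at all 3 stages and H3K27Ac at all 3, with no H3K4me3. A further wide iOL Brg1 peak on the same chromosome, at 173884725-173889057, also met Brg1 at all 3 stages, with Olig2 in OPC and iOL and with H3K4me3. The widest OPC Brg1 peak, at chromosome 8:43989855-43993327 (3.47 kb), met 2 iOL Brg1 peaks and no mOL Brg1 peak, with Olig2 in OPC and iOL. The peak at chromosome 5:123341439-123344473 was among the widest of OPC, and its overlapping mOL peak at 123341581-123344414 among the widest of mOL. The widest mOL Brg1 peak, at chromosome 1:135266007-135269271, met Brg1 in iOL, Olig2 in OPC and iOL, and H3K27Ac at all 3 stages. Among mOL Brg1 peaks with mOL Olig2, the widest lay at chromosome 13:75079535-75081981, where Brg1, Olig2 and H3K27Ac were each found at all 3 stages.

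Other targets had named sites of a different kind. The 3 widest mOL Olig2 peaks, at chromosome X:128955180-128959029, chromosome 14:21896495-21899240 and chromosome 9:802285-804945, met no Olig2 peak of an earlier stage and no H3K27Ac. The site on the X chromosome met H3K9me3 in OPC and mOL and no other target. Those on chromosomes 14 and 9 met no peak of any other list. Any control library is not given in the sources used here, so false calls cannot be told apart from Olig2 binding at these sites. Of RNAPII, the widest iOL peak at chromosome 8:69443579-69449076 (5.50 kb) met 2 OPC RNAPII peaks, H3K27Ac at all 3 stages and H3K4me3 in iOL and mOL. The widest mOL H3K4me3 peak, at chromosome 2:12272150-12284976 (12.8 kb), covered 3 separate H3K4me3 peaks in each of OPC and iOL. The widest mOL H3K9me3 peak, at chromosome 15:40037645-40046962 (9.32 kb), met 3 iOL H3K9me3 peaks and none in OPC.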

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

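The wider 50% of each list, the middle 200 bp of each peak and the equal-length H3K27Ac lists were chosen after seeing the data, as were the splits of Olig2 peaks by Brg1 and of Brg1 peaks by Olig2, the latter also with Olig2 of any stage, and the alternatives for unmarked peaks. No paired analysis was possible because each target and stage had 1 library. Restricting lists by the authors' score, and taking equal numbers of the highest-scoring peaks, were planned and not run, since the files hold no score. The gene-list alternatives were not run for want of an annotation of the same build. Library depth limits every list length and every share between lists, and its effect could not be measured here. Stage orders depended on the length of the H3K27Ac lists. From iOL to mOL acetylation, whole lists gave 49.2% and 59.2% of iOL Brg1 peaks and 32.3% and 40.7% of mOL Olig2 peaks, and equal-length lists 47.4% and 46.7%, and 30.8% and 29.9%. Values of main results that left the interval of the main value follow, and the cause was not tested beyond what each rule does by construction. Leaving out unplaced sequence moved none of 44 main results, and merging peaks within 1000 bp kept all 17 peak numbers within 1.5 times.

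Other results are given as counts outside their intervals. These were 18 of 43 with 50% overlap (17 lower), 23 of 43 within 1000 bp (22 higher), 38 of 43 with the wider 50% (23 higher, 15 lower), 27 of 27 with the middle 200 bp (25 lower), 6 of 8 with marks of any stage (4 higher) and 7 of 32 with each peak placed at random on its chromosome (3 higher, 4 lower). With equal-length H3K27Ac lists 8 of 14 were lower, among them mOL-gained Brg1 peaks with mOL H3K27Ac, 56.9% against 72.2%.

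With overlap of at least 50% of the shorter peak, shared peaks from OPC to iOL were 75.1% for H3K27Ac and 82.0% for H3K4me3, and from iOL to mOL 86.8% for H3K27Ac. The iOL odds ratio of Brg1 for Olig2 was 12.7. H3K27Ac without H3K4me3 was found at 66.7% of mOL Brg1, 23.2% of iOL Olig2 and 35.0% of mOL Olig2 peaks, and H3K4me3 at 63.0% of OPC and 65.2% of iOL RNAPII peaks. The other 18 of 27 main results stayed within their intervals.

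With peaks within 1000 bp counted as shared, OPC peaks met iOL peaks in 72.8% of cases for Olig2, 82.0% for H3K27Ac and 89.1% for H3K4me3, and iOL H3K27Ac peaks met mOL peaks in 90.8%. Brg1 of iOL met Olig2 in 75.4%, with odds ratios of 13.0 in iOL and 14.0 in mOL. The enhancer-type share of iOL Olig2 was 25.3%, and H3K4me3 was at 77.7% of iOL RNAPII peaks. Gained Brg1 peaks met earlier Olig2 in 74.98% of cases in iOL and 52.8% in mOL.

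With the wider 50% of each list, OPC peaks met iOL peaks in 87.2% of cases for Brg1, 61.7% for Olig2, 37.1% for RNAPII, 69.7% for H3K27Ac and 74.3% for H3K4me3. From iOL to mOL the values were 37.3% for Brg1, 8.22% for Olig2, 83.5% for H3K27Ac, 96.2% for H3K4me3 and 50% for H3K9me3. Brg1 met Olig2 in 70.3% of cases in iOL, with an odds ratio of 13.3, and in 17.7% in mOL. For the odds ratio and the enhancer-type shares, the mark lists were left whole. Enhancer-type shares in OPC, iOL and mOL were 82.3%, 63.3% and 81.0% for Brg1 and 34.2%, 36.9% and 46.8% for Olig2.

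With the middle 200 bp of each peak, which shortens every peak, OPC peaks met iOL peaks in 70.6% of cases for Brg1, 63.1% for Olig2, 42.2% for RNAPII, 51.6% for H3K27Ac, 66.7% for H3K4me3 and 3.46% for H3K9me3. From iOL to mOL the values were 30.4% for Brg1, 9.11% for Olig2, 54.6% for H3K27Ac, 65.9% for H3K4me3 and 20.1% for H3K9me3. Brg1 met Olig2 in 67.7% of cases in OPC, 55.4% in iOL and 18.0% in mOL. Over H3K27Ac peaks of full width, the odds ratios were 35.1 in OPC and 13.6 in iOL.

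With marks of any stage, enhancer-type shares in OPC, iOL and mOL were 73.7%, 59.2% and 73.8% for Brg1 and 33.5%, 34.9% and 44.5% for Olig2, and H3K4me3 was at 79.8% of OPC and 84.4% of iOL RNAPII peaks. Within quartiles of H3K27Ac width the iOL odds ratio was 13.8. Placement inside regions with H3K27Ac or H3K4me3 was set against all Brg1 peaks, marked or not. Brg1 then met Olig2 at 3.19 times the chance value in OPC, 2.09 times in iOL and 6.97 times in mOL. The H3K27Ac shares of Olig2 peaks with Brg1 stayed above those without it at each stage under each of the 6 rules tried. The lowest share with Brg1 was 51.6%, against 22.0% without, in iOL. It came with the middle 200 bp of Olig2 and Brg1 peaks and H3K27Ac peaks of full width.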

Other observations

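The tests of peak width for mOL Olig2 and of OPC-only Olig2 peaks, the control with Olig2 at both stages, the shares of gained and lost sites whose acetylation changed, the equal-length H3K27Ac lists, and the comparison groups described in the next paragraphs, were chosen after the results they concern had been seen.

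H3K4me3 places called in mOL alone differed from those present throughout. The 5942 mOL-only H3K4me3 peaks were narrow, with a median of 581 bp against 1364 bp for the 9055 mOL peaks that met both earlier lists, and met mOL H3K27Ac in 49.2% (47.9 to 50.5) of cases against 94.5% (94.0 to 94.97). In the unsorted mOL H3K4me3 list, 98.3% (97.6 to 98.9) of the first 1753 peaks met an OPC H3K4me3 peak and 6.67% (5.55 to 7.95) of the last 1753. A more sensitive mOL library could also add narrow peaks, and the lists do not separate this from new H3K4me3. In OPC, 28.8% (27.6 to 29.9) of the mOL-only places carried H3K27Ac. RNAPII of iOL was found at 3.48% (3.03 to 3.98) of them and at 13.1% (12.4 to 13.8) of the places present throughout. Brg1 of mOL was rare at both, with 2.27% (1.91 to 2.68) and 1.18% (0.969 to 1.43).

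The Olig2 sites called in mOL alone met H3K9me3 more often, and H3K27Ac less often, than mOL sites present in iOL, though most of them met neither mark in mOL. Of 161 such peaks, 16.1% (10.8 to 22.8) met H3K9me3 in OPC and 9.32% (5.31 to 14.9) in mOL, against 0.274% (0.110 to 0.563) and 0.547% (0.299 to 0.916) of the 2559 mOL Olig2 peaks present in iOL. H3K27Ac of mOL was found at 9.32% (5.31 to 14.9) of the former and 43.0% (41.1 to 44.9) of the latter. Without a known control library, false calls among the 161 peaks cannot be told apart from Olig2 binding. Brg1 peaks of mOL without Olig2 at any stage numbered 1125, or 25.7% (24.4 to 27.02) of the list, and these places were acetylated more often at later stages, at which the H3K27Ac lists were also longer: 9.51% (7.86 to 11.4) met H3K27Ac in OPC, 28.5% (25.9 to 31.3) in iOL and 68.4% (65.6 to 71.2) in mOL. With H3K27Ac lists of equal length the shares were 9.51% (7.86 to 11.4), 26.6% (24.0 to 29.3) and 51.6% (48.7 to 54.6).

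The shares on the X chromosome differed between lists, from 0.434% (0.261 to 0.677) of mOL Brg1 peaks to 4.82% (2.78 to 7.71) of OPC RNAPII peaks. In the unsorted Olig2 list of iOL, 98.6% (98.0 to 99.0) of the first 2579 peaks met an OPC Olig2 peak and 33.6% (31.8 to 35.5) of the last 2578. Not every unsorted list was of this form. In the mOL Olig2 list, 89.9% (85.7 to 93.2) of the first 276 and 88.4% (84.0 to 91.9) of the last 275 met an iOL Olig2 peak. In the mOL Brg1 list the first peaks were narrower than the last, with medians of 767 bp and 1099 bp.

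The OPC Brg1 list was short and lay almost wholly inside the iOL list. As the whole cause of the longer iOL list, new acetylation in iOL is argued against by earlier acetylation. It was called in OPC at 42.4% (41.0 to 43.8) of the 5009 gained sites. Acetylation in iOL alone was found at 680 of them (13.6%, 12.6 to 14.6), or 13.5% within 1000 bp and 12.6% with equal-length H3K27Ac lists. Since 48.0% of gained sites met iOL H3K27Ac at all, this share could not have reached most sites and decides nothing by itself. Lower sensitivity of the OPC library as a cause of the short list stays open. Peaks of iOL that met an OPC peak had a median width percentile of 68.9 (66.1 to 73.2) within the iOL list, with medians of 1192 bp against 967 bp. Wider peaks meet another list more readily, so this value does not tell lower sensitivity from a gain of sites. New acetylation as a part of the cause stays open: at gained sites, acetylation in iOL alone was 1.70 times as frequent as in OPC alone, against 2.13 at iOL Olig2 peaks without Brg1, a ratio of 0.801 (0.692 to 0.928). That control was itself picked on iOL occupancy, and with Olig2 present at both stages in both groups the ratio was 1.19 (0.995 to 1.42), so the controls disagree.

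The mOL Olig2 list was short and lay inside the iOL list in the same way. Loss of acetylation is argued against as the whole cause by lost sites that stayed acetylated. Of 23216 lost sites, 22.2% (21.7 to 22.7) were acetylated in both iOL and mOL. Acetylation in iOL and not in mOL was found at 939 of them (4.04%, 3.79 to 4.31), or 4.01% within 1000 bp and 6.65% with equal-length H3K27Ac lists. Since 26.2% of lost sites were acetylated in iOL at all, this share could not have reached most sites and decides nothing by itself. Acetylation in mOL and not in iOL was found at 10.7% (10.3 to 11.1). With equal-length lists it was found at 6.21% (5.90 to 6.52), which ends that excess. Peaks of iOL that met an mOL peak had a median width percentile of 71.0 (69.3 to 72.8). Since wider peaks meet another list more readily, this value does not tell a less sensitive mOL library from a loss of sites. Loss with acetylation as a part of the cause stays open: acetylated iOL Olig2 peaks were acetylated again in mOL in 84.6% of 6093 cases without mOL Olig2 and 86.0% of 899 cases with it, an odds ratio of 0.895 (0.732 to 1.09). A lower level of Olig2 protein in mOL was not tested.

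Olig2 peaks of iOL that were already present in OPC held iOL Brg1 more often than those gained later, with an odds ratio of 7.73 (6.93 to 8.61). A candidate explanation is that the older peaks are merely the stronger ones. The iOL list was parted into 10 by its row order. Row order was taken as a proxy for strength because early rows were wider and more often shared. The odds ratio was then 5.56 (4.95 to 6.25), which argues against strength so measured as the whole cause. Sharing with OPC is also the property compared here, and the meaning of the row order is not given. Strength itself may therefore not have been held equal. OPC Olig2 peaks without an iOL Olig2 peak held iOL Brg1 in 7.12% of cases and gained iOL Olig2 peaks in 3.73%, an odds ratio of 1.98 (1.71 to 2.28) with peaks reduced to their middle 200 bp. With peaks as called these shares were 7.45% and 3.82%, both far below the 23.5% (22.8 to 24.2) of iOL Olig2 peaks kept from OPC. The order goes with the hypothesis that Olig2 occupancy in OPC marks places where Brg1 is called in iOL. General openness of these places was not tested. Nor were peak strength in this comparison and Brg1 or Olig2 that was present but not called.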
